A study of Mus musculus with 9 samples.

How the data were processed

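Single-cell RNA sequencing was run on dura mater, the outer membrane around the brain, from the heads of mice 12 days after inoculation. Per the labels, 3 groups were sampled with 3 libraries each: nontumor mice, mice with leptomeningeal metastasis (LM) and mice with dural metastasis (DM) of 4T1, a mouse mammary carcinoma line. Per the labels, the tissue was digested to single cells with collagenase and DNase, tissue of 6 mice was pooled for each group, and the libraries were made with droplet kits of 10x Genomics. The labels do not say how the mice were divided among the 3 libraries of a group, so the p-values measure the spread between these libraries.

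Per the labels, the DM libraries were made from tumor-bearing dura with a 3' v2 kit, and the nontumor and LM libraries with a 5' kit. Kit and group cannot be told apart in any comparison with DM, while LM and nontumor share a kit. The deposited values are counts: raw UMI counts per gene and cell, without normalization. All values were whole numbers. Per the file headers, the DM counts were made with Cell Ranger 7.1.0, and the headers of the other libraries name no software. Per the submitters' processing notes, Cell Ranger 2.1.1 and the genome build mm10 were used. Barcodes had 16 characters in the DM libraries and 17 in the others. Every barcode had at least 500 UMIs, so droplets under that cut are absent. Whether droplets without a cell lie above it was not tested. Free RNA in the suspension was estimated from the cells themselves. The deposited gene tables carry other information only, namely the names of genes and barcodes. They list 31253 genes for DM and 32285 for nontumor and LM, with 30999 shared Ensembl identifiers. Because 273 shared identifiers carry another symbol in each table, genes were joined by identifier. Positions (1-based, mm10) come from the GENCODE M21 annotation, which gave a position for 32158 identifiers.

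Cells with fewer than 250 genes or more than 15% mitochondrial UMIs were left out. Doublets were called in each library with Scrublet in scanpy 1.11.5 (Python 3.11.15) at an expected rate of 0.08 and a fixed score of 0.25, because the automatic threshold called no doublet in some libraries. Doublets were 2.45% to 4.37% of the cells of a library. The cells kept numbered 12371, 12692 and 13286 in DM, 13104, 14584 and 11962 in LM, and 7803, 11843 and 11554 in nontumor. The 5' libraries and the 3' libraries were clustered separately (2500 variable genes, 40 principal components, 20 neighbours, Leiden clustering in igraph 0.11.9 at resolution 2 for the 5' and 3 for the 3' libraries). This gave 89 and 72 clusters after mixed clusters were divided, of which 77 and 58 received a name.

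Clusters were named from markers of 25 cell classes fixed before the data were examined. A cluster took a class if the mean scaled expression of its markers was at least 0.5, at least 3 markers were detected in 10% of its cells, and no other class led its 10 top genes. The class taken was not always the best-scoring one. A class within 0.15 of the best score, or the class that led the top genes, could also be taken. Clusters with over 40% doublets or fewer than 20 other cells stayed unnamed, as did clusters with low UMI counts and no own marker among the top genes. The naming rule went through 6 versions with the number of cells per class and library in view and before any comparison of groups. The Scrublet score, the clustering resolution, the naming thresholds and 2 added classes, pinealocytes and olfactory cells, were set after seeing the data. Unnamed clusters held 17.7% ± 8.26 (SD, n = 3) of the cells in DM, 2.60% ± 0.333 in LM and 2.76% ± 0.464 in nontumor. Most of the unnamed DM cells, 14.7% ± 12.6 of all DM cells, lay in clusters whose leading genes belonged to a class other than the best-scoring one. Tumour-like cells are the cells of clusters named from Epcam, keratin and claudin genes. Erythroid cluster 14 (21 LM and 7 nontumor cells) holds Ccl8, Ccl7 and C1qa beside haemoglobin genes in its top 10. Tumour-like cluster 49.4 (22 DM cells) holds Ccl2, Mgl2 and Arg1 there and no Epcam, keratin or claudin gene. Both were kept in the shares.

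Shares of cells were compared with edgeR 4.0.16 (R 4.3.3) by a quasi-likelihood test on the cells per class and library, with the library's cells kept as offset. Classes with under 10 cells on average were left out, and the adjusted p (Benjamini-Hochberg, threshold 0.05) covers the classes of a comparison. An exact two-sided permutation p, whose smallest possible value for 3 against 3 libraries is 0.1, stands beside the test. For shares of a single library, 95% Clopper-Pearson intervals and a floor of 3 cells were computed; intervals and floors cover counting error only. Folds against a group at 0 are given as "at least", against a floor of 3 counts over the group.

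Gene tests covered 6 classes fixed before the data were examined: neutrophils, monocytes and macrophages summed (called monocyte-macrophages), B cells, T cells, fibroblasts and endothelial cells. UMIs were summed per library and class, with at least 20 cells, and tested with edgeR (TMM normalization, filterByExpr, quasi-likelihood). A gene was called at an adjusted p below 0.05 with a log2 fold of at least 1 in either direction. It was set aside where free RNA could supply it, that is, where its CPM (UMI counts scaled to a common library total) in the class was under 0.2 of the CPM of the whole library. In comparisons with DM, a second test had to pass in the same direction. There, limma 3.58.1 tested the class-relative value: log2 CPM (prior count 2) in the class minus its mean in the other classes. A gene entered this test only if it passed the filter in at least 2 other classes. Genes restricted to a class could therefore not be called in comparisons with DM. Of 15289 genes tested in fibroblasts between DM and nontumor, 10651 entered it. Where a gene is well counted, a kit effect common to the classes cancels in that value, and so does a change common to the classes. For a gene with few or no counts in DM, the prior count bounds the fall. A loss common to the classes then cancels only in part. B cells were not tested in DM, where 1 library held at least 20 of them. Named genes were taken, per class, from the 2 with the largest rise and the 2 with the largest fall among called genes whose libraries do not overlap between groups (3 against 3 libraries do so by chance in 10% of genes), plus the 2 to 4 list members with the smallest p.

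Lists of genes fixed before the data were examined (19 lists) were tested with camera in limma at a preset correlation of 0.01 and at an estimated correlation, and with fry. For a list, the members that rose or fell are those past an adjusted p of 0.05 over all genes of the class, without the fold threshold or the free-RNA rule. In the comparison of DM with nontumor, the lists use the class-relative values, and their measured members are those that entered that test. How many members rose or fell by the plain fold, and which lay under the free-RNA limit, was counted after those results had been seen.

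Simulated changes in 200 genes of T cells were tested the same way. In the comparison of LM with nontumor, 37.3% of 2-fold, 100% of 4-fold and 98.5% of 8-fold changes were recovered, with 6 of 10554 unchanged genes called. With DM in place of LM, the shares were 10.4%, 77.6% and 92.3%, with 2 of 8547. The simulated kit effect of a gene was the same in all classes, and the spread between libraries was the same for all genes. Changed genes were drawn above a minimum CPM. A kit effect that differs between classes, and losses from all classes as large as those seen in DM, were not simulated. The shares therefore do not measure how well the kit is removed in the real libraries. The alternatives tried were 500 genes per cell, doublets kept, marker scores per cell in place of clusters, other denominators and normalizations, DESeq2 1.42.0, no filter on low counts, no fold threshold, no free-RNA rule, all 9 libraries in 1 fit, the replicate number as a block, each library left out in turn, and either DM test alone. Settings chosen after seeing the data were naming without the added classes, the first naming rule, and unnamed cells left out of the denominator.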

Results

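The 9 libraries of mouse dura mater, 3 each from nontumor mice, mice with leptomeningeal metastasis (LM) and mice with dural metastasis (DM), were compared for their cell types and for gene expression within cell types. Total UMIs were 79733707, 83185997 and 80368085 in nontumor replicates 1 to 3, 107863908, 123275821 and 90791932 in LM, and 228630442, 159548593 and 105116623 in DM. Median UMIs per kept cell were 5995, 4749 and 4360.5 in nontumor, 5579, 4807 and 4937.5 in LM, and 12271, 8738.5 and 4035 in DM. Values with ± are means and standard deviations over the 3 libraries of a group (n = 3), unless they are named as log2 folds with standard errors. Adjusted p-values are from edgeR or limma as described under the processing.

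Whether carcinoma cells were present in each dura was read from clusters with the epithelial genes Epcam, Krt8, Krt18 and Krt7, genes of epithelial carcinoma cells. Such tumour-like cells were 36.4% ± 10.4 of the cells in DM (n = 3), 3.70% ± 2.99 in LM and 0 in nontumor. The DM libraries held 41.1% (95% Clopper-Pearson interval 40.2% to 41.9%), 43.6% (42.8% to 44.5%) and 24.4% (23.7% to 25.2%), and the LM libraries 0.748% (0.608% to 0.911%), 6.72% (6.32% to 7.14%) and 3.62% (3.29% to 3.97%). In nontumor replicates 1 to 3, with 0 cells each, the upper limits of that interval were 0.0473%, 0.0311% and 0.0319%. The floor of 3 cells lay at 0.0384%, 0.0253% and 0.0260%. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give, for LM and for DM against nontumor. In the tumour-like cells, Krt18, a cytoskeletal keratin, stood at 1043 CPM ± 2.00 in LM and 2402 ± 122 in DM, against 3.23 ± 2.83 in whole nontumor libraries. Epcam, an epithelial adhesion molecule, stood at 394 CPM ± 159 in LM and 587 ± 355 in DM tumour-like cells and at 5.19 ± 4.49 in whole nontumor libraries. In an early version of the naming rule a few nontumor cells with olfactory genes counted as tumour-like. The nontumor share was 0 with the first naming rule on the final clusters, but 0.318% ± 0.171 with marker scores per cell and 0.542% ± 0.693 when UMIs of 3 tumour markers sufficed.

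The comparison of LM with nontumor dura asks which cells and genes change in the dura when carcinoma grows in the inner meninges. Whether cells of the LM libraries came from the dura itself or from inner meninges carried along in the dissection was not tested. T cells rose from 2.03% ± 0.214 of the cells in nontumor to 8.22% ± 2.02 in LM (n = 3), a log2 fold of 2.02 (SE 0.29, adjusted p = 0.00347), and were higher in 3 of 3 LM libraries than in every nontumor library. B cells fell from 11.6% ± 1.97 to 2.33% ± 1.03, by 2.31 on the log2 scale (SE 0.39, adjusted p = 0.00433). Macrophages rose from 8.70% ± 0.941 to 14.1% ± 1.37, dendritic cells from 2.15% ± 0.278 to 3.79% ± 0.516, NK or innate lymphoid cells from 1.31% ± 0.316 to 2.59% ± 0.337, and plasmacytoid dendritic cells, the producers of type I interferon, from 0.569% ± 0.265 to 1.30% ± 0.257. Schwann or glial cells fell from 6.48% ± 1.72 to 2.13% ± 0.616, erythroid cells from 1.70% ± 1.47 to 0.291% ± 0.184, and mast cells or basophils from 0.321% ± 0.136 to 0.0889% ± 0.0234. Tumour-like cells were at least 384-fold higher in LM (adjusted p = 0.00433), a bound for counts of named cells that does not hold with marker scores per cell (log2 fold 3.71). Shares of fibroblasts (27.9% ± 7.91 in LM, 29.0% ± 9.22 in nontumor), arachnoid barrier cells (12.3% ± 0.868 and 11.6% ± 5.55), endothelial cells (5.18% ± 0.341 and 6.94% ± 2.09) and neutrophils (5.64% ± 0.690 and 6.27% ± 3.26) did not pass the test.

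Of the 19 classes tested between LM and nontumor, 10 passed in edgeR, and the exact permutation p of each of these was 0.1. The adjusted p-values were 0.0435 for macrophages, 0.0342 for dendritic cells, 0.0327 for NK or innate lymphoid cells, 0.0416 for plasmacytoid dendritic cells, 0.0102 for Schwann or glial cells, 0.0342 for erythroid cells and 0.0117 for mast cells or basophils. The calls of T cells, B cells and tumour-like cells held without any 1 of the libraries. Those of NK or innate lymphoid cells, dendritic cells, macrophages and plasmacytoid dendritic cells ended without nontumor replicate 2, nontumor replicate 3, or any 1 LM library, with log2 folds of 0.83 to 1.08, 0.70 to 0.89, 0.62 to 0.79 and 0.89 to 1.30. The erythroid call ended without nontumor replicate 1 (log2 fold -1.53), LM replicate 2 (-2.92) or LM replicate 3 (-2.09), the mast cell call without LM replicate 2 (-1.67) or 3 (-1.79), and the Schwann cell call without LM replicate 3 (-1.63). Without LM replicates 1, 2 and 3 in turn, 6, 4 and 3 classes passed, and 6 passed without nontumor replicate 3. With marker scores per cell, mast cells or basophils (-0.60, adjusted p = 0.282), NK or innate lymphoid cells (0.41, adjusted p = 0.232) and macrophages (0.56, adjusted p = 0.0678) did not pass. The macrophage call also ended with TMM over class counts (0.84, adjusted p = 0.0755) and without tumour-like and erythroid cells (0.74, adjusted p = 0.0530). The replicate block ended the calls of macrophages (0.70, adjusted p = 0.180), dendritic cells (0.81, adjusted p = 0.120) and NK or innate lymphoid cells (1.00, adjusted p = 0.0617). With all 9 libraries in 1 fit, 4 passed, and the B cell fall kept its size with an adjusted p of 0.0813.

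**Figure D1:**
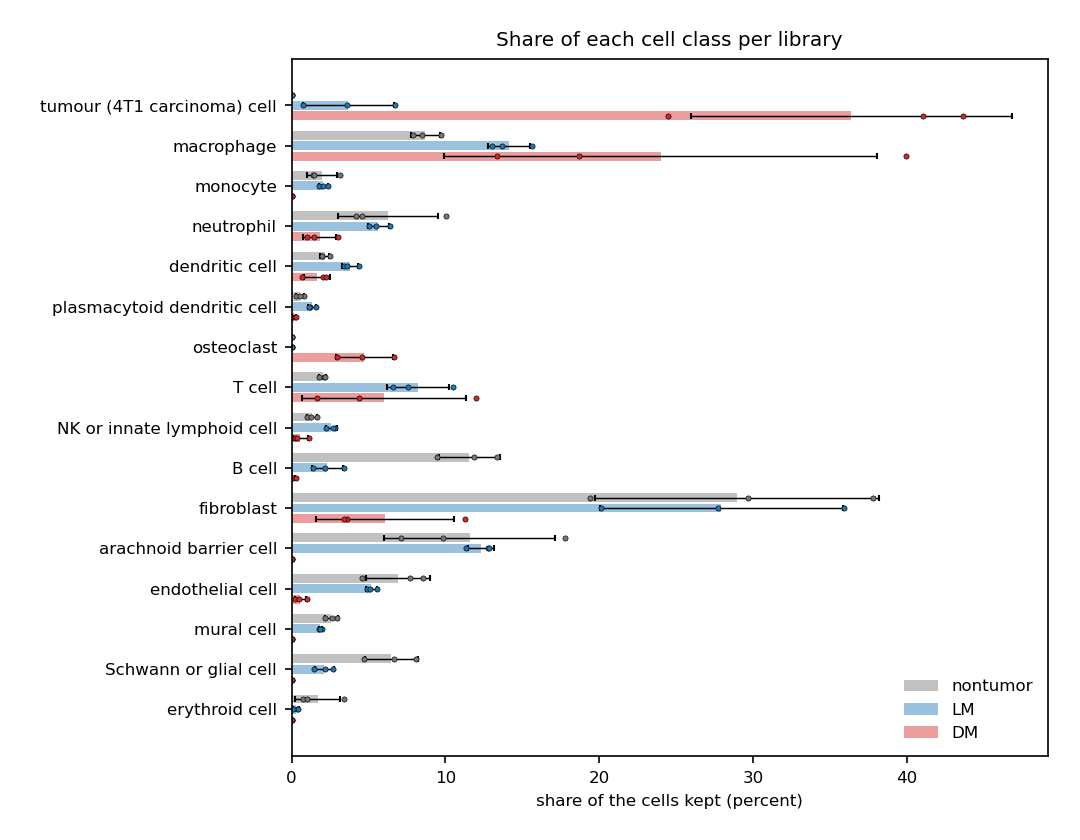
Share of each cell class among the cells kept, in percent, for nontumor (grey), LM (blue) and DM (red). Bars are means, points are the 3 libraries of a group and black lines span 1 SD either side, so that T cells sit at 2.03% in nontumor and 8.22% in LM, and tumour-like cells at 36.4% in DM.

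T cells of LM dura expressed cytotoxic, activation and proliferation genes at higher levels. Gzmb, the granzyme of killer cells (chromosome 14, 56258838 to 56262260), rose from 11.6 CPM ± 6.60 to 687 ± 197 (n = 3), a log2 fold of 5.99 (SE 0.33, adjusted p = 4.6e-06), and Ifitm1, an interferon-induced membrane protein, by a log2 fold of 5.94 (SE 0.70). With 1 library left out, the log2 fold of Ifitm1 ranged from 5.41 to 12.61, the highest without nontumor replicate 3. Of 17 members of the T cell activation and exhaustion list, 12 rose and 1 fell, and 12 and 1 when adjusted over the list alone (adjusted p = 0.296 with an estimated correlation). Among them were Havcr2 (log2 fold 5.87), an inhibitory receptor, Prf1 (3.42), the pore protein perforin, and Ctla4 (1.55), while Tox fell. Of 20 cell cycle genes, 19 rose, among them Ube2c (2.61), Ccnb2 (2.29) and Mki67 (1.88), and 20 when adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). All 10 measured naive T cell genes fell, 10 also when adjusted over the list alone (adjusted p = 0.296 with an estimated correlation), with the transcription factor Bach2 at a log2 fold of -1.40 and S1pr1, the receptor for exit from tissue, at -1.09. The largest falls were those of Stab2, a scavenger receptor (-4.69), and Adcyap1, a neuropeptide (-4.35). The call of Adcyap1 ended without nontumor replicate 1 (-2.21) and with DESeq2 (-4.22, adjusted p = 0.0639). Cluster 30, led by Ctla4 and Icos, was the largest T cell cluster in both groups, with 58.0% of LM and 48.1% of nontumor T cells. The rest differed: cluster 50, led by Cd8b1, Gzmb and Ccl5, held 23.6% and 5.57%, cluster 20, led by histone genes, Mki67 and Top2a, held 11.5% and 2.23%, and cluster 44, led by the gamma-delta T cell genes Trdv4, Il23r and Cd163l1, held 6.91% and 44.1%.

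B cells remaining in LM dura had lower levels of early developmental genes and higher levels of antigen presentation genes. Dntt, which adds nucleotides at recombining antibody genes (chromosome 19, 41029275 to 41059525), fell from 69.8 CPM ± 13.3 to 4.60 ± 2.53 (n = 3), by 3.66 on the log2 scale (SE 0.31, adjusted p = 0.000477). In the B cell development list 8 of 10 genes fell, among them the surrogate light chain genes Igll1 (-1.88) and Vpreb1 (-1.56) and the recombinase gene Rag1 (-1.53), and 9 when adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). All 10 MHC class II presentation genes rose, 10 also when adjusted over the list alone (adjusted p = 0.296 with an estimated correlation), among them Cd86 (1.90), H2-Aa (1.66) and Cd74 (1.32). Of 11 mature B cell genes 5 rose, among them Cr2 (1.57), and 1 fell; adjusted over the list alone these were 8 and 1 (adjusted p = 0.348 with an estimated correlation). Serpina3g, a protease inhibitor, rose by a log2 fold of 5.64 (SE 0.57), with a range of 5.20 to 6.66 with 1 library left out. Cacna1s, a calcium channel subunit, had 52 UMIs in LM and 1 in nontumor, a ratio of CPM of 269.9 (counting interval 46.3 to 10861). Mmrn1, an endothelial matrix protein, was at least 5.12-fold lower in LM, a call that ended without LM replicate 1 or 2 (adjusted p = 0.0653 and 0.0767). Cluster 21, led by Ms4a1, Bank1 and Ccr7, held 58.9% of LM and 11.9% of nontumor B cells, whereas 47.6% of the nontumor and 19.7% of the LM B cells lay in cluster 34, whose top 10 genes hold Ms4a1, Vpreb3 and Bank1. Cluster 0, led by Vpreb3 and with Rag1 in its top 10, held 30.5% of the nontumor and 14.8% of the LM B cells.

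Monocyte-macrophages of LM dura rose in glycolysis and antigen presentation genes, and their largest rises were those of Arg1 and Cxcl13. Arg1, which breaks down arginine (chromosome 10, 24915221 to 24927484), rose from 1.32 CPM ± 2.08 to 195 ± 81.3 (n = 3), a log2 fold of 7.34 (SE 0.68, adjusted p = 0.000346), and Cxcl13, an attractant of B cells, by 7.17 (SE 0.39). With 1 library left out, Arg1 ranged from 6.75 to 10.63, the highest without nontumor replicate 2, and Cxcl13 from 6.65 to 8.35. In the NF-kB inflammatory list 5 of 18 genes rose and 4 fell, and 5 and 5 when adjusted over the list alone, and the list did not pass (adjusted p = 0.727). In the tumour-associated macrophage list 9 of 17 genes rose, among them Nos2 (6.91), an enzyme that makes nitric oxide, Cd274 (2.46), which encodes PD-L1, and Mmp14 (2.60), and Cxcl3, Hmox1 and Thbs1 fell. Adjusted over the list alone, 9 rose and 4 fell (adjusted p = 0.344 with an estimated correlation). Of 20 glycolysis and hypoxia genes 17 rose, among them Mif (1.79) and Bnip3 (1.41), and 17 when adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). MHC class II presentation genes rose in 8 of 10 cases, among them Ciita (1.80), their transactivator, and 9 rose when adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). Of 15 genes of resident border macrophages 5 fell, among them Cd209f (-2.18), Ccl24 (-1.92) and Pf4 (-1.74), and 6 when adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). Ugt8a, an enzyme of myelin lipid synthesis, fell (-4.28); its call ended without nontumor replicate 1 (-3.78) and with marker scores per cell (-3.18), and Schwann or glial cells were fewer in LM. Cluster 43, led by C1qa, Ccl5 and Arg1, held 24.4% of LM and 0.182% of nontumor macrophages. Cluster 41, led by Mrc1, held 21.9% and 44.7%, and cluster 29, led by Ccl8 and Pf4, held 5.78% and 26.05%. The class thus differs in its clusters.

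Neutrophils of LM dura rose in Wfdc17 and in interferon genes (12 of 19 measured, adjusted p = 0.296 with an estimated correlation). Wfdc17, a secreted protein of activated myeloid cells, rose from 23.6 CPM ± 10.2 to 1891 ± 746 (n = 3), a log2 fold of 6.43 (SE 0.43, adjusted p = 8.27e-05), and Ambp was at least 20.4-fold higher. In the NF-kB inflammatory list 5 of 18 genes rose, among them the chemokines Ccl4 (2.16) and Ccl3 (1.70) and the cytokine Tnf (1.18), and 9 when adjusted over the list alone; fry did not call the list (adjusted p = 0.175, and 0.417 with an estimated correlation in camera). Of 14 genes of the aged and tumour-associated neutrophil list 3 rose, and Cxcr4, the receptor that retains neutrophils in marrow, fell (-0.73); adjusted over the list alone 7 rose and 1 fell, and fry did not call the list (adjusted p = 0.212, and 0.436 with an estimated correlation in camera). The neutrophil granule list did not pass (adjusted p = 0.828), with 2 of 14 genes higher. Cluster 16, led by the immature granule genes Camp and Ngp, held 25.2% of LM and 38.8% of nontumor neutrophils, and cluster 3, led by Retnlg and S100a9, held 64.9% and 50.9%, so the class differs in its clusters. Thbs1, thrombospondin, fell by 3.40 on the log2 scale (SE 0.30) and Ces1d, a carboxylesterase, by 3.29 (SE 0.67). The call of Ces1d ended without nontumor replicate 2 or 3 or any 1 LM library (-4.10 to -2.67).

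Fibroblasts of LM dura rose in part of the matrix genes. Collagen and matrix genes rose in 9 of 19 cases, among them Timp1 (log2 fold 1.06), an inhibitor of matrix proteases, and Tnc (1.03), tenascin C, and 9 when adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). In the fibroblast chemokine and cytokine list 6 of 18 genes rose, among them Cxcl12 (1.24), and 3 fell, among them the neutrophil attractant Cxcl5 (-2.29). Adjusted over the list alone these were 8 and 4, and the list did not pass camera (adjusted p = 0.0633). Serpina3n, a protease inhibitor of the acute phase (chromosome 12, 104406729 to 104414329), rose from 0.808 CPM ± 0.498 to 7.04 ± 1.98 (n = 3), a log2 fold of 3.14 (SE 0.44, adjusted p = 0.0044), and Lrr1 by 3.26 (SE 0.57). Spocd1 fell with a log2 fold of -4.50 (SE 0.71) and Fer1l5 with -3.64 (SE 0.60). Of 18 immediate early and heat shock genes 9 fell, among them Atf3 (-1.50) and Jun (-1.12), and 10 when adjusted over the list alone, with 1 then higher. The median log2 fold of that list was -0.565, and fry did not call it (adjusted p = 0.155, and 0.510 with an estimated correlation in camera).

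Endothelial cells of LM dura rose in Ackr1 and Vcam1, which bind chemokines and leukocytes. Ackr1, a chemokine receptor of venules, rose from 60.5 CPM ± 13.4 to 413 ± 144 (n = 3), a log2 fold of 2.80 (SE 0.26, adjusted p = 0.00185), and Vcam1, which captures leukocytes, by 0.97 (SE 0.18). Cluster 55.5, led by Apold1, Ackr1, Lrg1, Sele and Selp, held 3.22% of LM endothelial cells and none of nontumor. Ackr1 and Vcam1 were 2 of 10 measured leukocyte adhesion genes, and 3 rose when adjusted over the list alone (adjusted p = 0.296 with an estimated correlation). Serpina3n rose by a log2 fold of 3.71 (SE 0.62), a call that ended without nontumor replicate 2 (3.94) or 3 (3.31). Ubd, a ubiquitin-like protein induced by interferon-gamma, had 528 UMIs in LM and 2 in nontumor, a ratio of CPM of 312 (counting interval 86.0 to 2585). Its call ended without any 1 nontumor library (adjusted p of 0.108, 0.197 and 0.2005 without replicates 1, 2 and 3), with marker scores per cell (0.0608) and with all 9 libraries in 1 fit (0.0901). Fst, follistatin, fell by 3.29 on the log2 scale (SE 0.53) and Gkn3 by 3.10 (SE 0.33). The call of Fst ended without nontumor replicate 2 or 3 or LM replicate 2 or 3 (-3.50 to -2.76), with marker scores per cell (-1.93) and with all 9 libraries in 1 fit (-3.26, adjusted p = 0.0594). In the angiogenesis list 1 of 13 genes passed, the insulin receptor gene Insr (0.91), and the list did not (adjusted p = 0.812).

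Interferon response genes rose in LM in 5 classes by camera at the preset correlation and by fry, and no test compared the classes with each other. The counts were 12 of 19 measured genes in neutrophils, 15 of 20 in monocyte-macrophages, 10 of 14 in B cells, 10 of 19 in T cells, 13 of 20 in fibroblasts and 5 of 20 in endothelial cells, and none fell. Of these risers 2, 0, 5, 2, 2 and 0 lay under the limit of 0.2 for free RNA, which the lists do not apply. In endothelial cells fry did not call the list (adjusted p = 0.238), and the median rise over the list was 0.115 of the rise that free RNA allows. In B cells, T cells and fibroblasts the lower quartile of that ratio was under 1. Adjusted over the list alone they were 16, 15, 12, 10, 15 and 5, and with an estimated correlation the adjusted p-values were 0.296, 0.344, 0.296, 0.379, 0.301 and 0.477. Gbp2, an interferon-induced GTPase, rose by log2 folds of 2.80 (SE 0.16) in monocyte-macrophages, 2.46 in neutrophils, 2.43 in B cells and 1.60 in endothelial cells.

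Over the 6 classes, 3707 of 71286 gene tests between LM and nontumor were called, with 1706 rises and 2001 falls. The classes held 1203 (552 rises and 651 falls) in T cells, 861 (225 and 636) in fibroblasts, 836 (390 and 446) in monocyte-macrophages, 428 (310 and 118) in B cells, 233 (133 and 100) in neutrophils and 146 (96 and 50) in endothelial cells. With all 9 libraries in 1 fit the total was 2390. Without LM replicate 3 the neutrophil count was 67, without nontumor replicate 2 the counts were 246 in B cells, 510 in fibroblasts and 77 in endothelial cells, without LM replicate 2 the fibroblast count was 547, and without nontumor replicate 3 the endothelial count was 84. Of 46 pairs of list and class, camera at the preset correlation called 33 (26 higher and 7 lower in LM), fry 22, and camera with an estimated correlation 0. At the preset correlation every other split of the same 6 libraries called between 18 and 25 pairs, so the gene counts above carry the description of the lists. Median, mean and test differed in sign for 3 pairs: the NF-kB list in monocyte-macrophages and T cells and the immediate early list in endothelial cells.

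**Figure D2:**
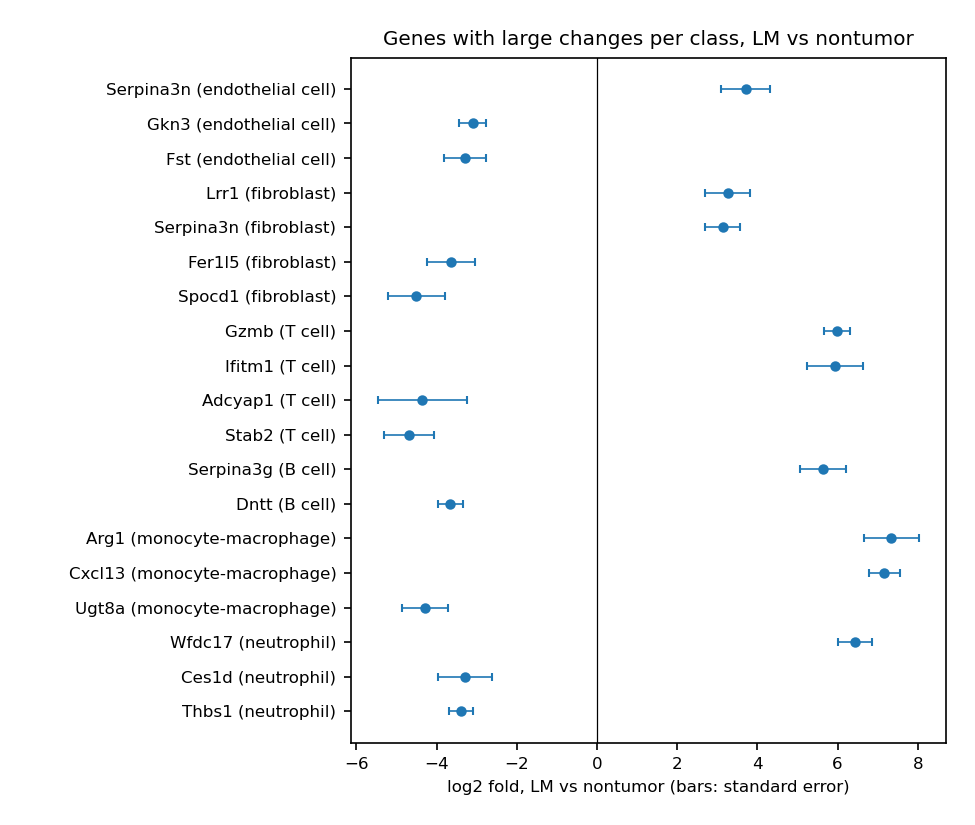
Log2 fold of LM over nontumor (horizontal axis) for genes among those with the largest rise or fall in each class, without genes that had 3 or fewer UMIs in a group. Points are edgeR estimates and bars their standard errors, so that Arg1 lies at 7.34 in monocyte-macrophages and Dntt at -3.66 in B cells.

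The comparison of DM with nontumor dura asks how the dura differs where the carcinoma grows in it, and every value in it carries the difference between the 3' and 5' kits. Osteoclasts, the cells that resorb bone, were 4.73% ± 1.86 of the cells in DM (n = 3) and 0 in nontumor, at least 492-fold higher (adjusted p = 5.57e-12). Tumour-like cells were at least 3784-fold higher (adjusted p = 1.57e-14). Neither bound holds with marker scores per cell, where the log2 folds were 3.05 for osteoclasts and 6.34 for tumour-like cells. B cells fell from 11.6% ± 1.97 to 0.106% ± 0.139 (log2 fold -6.74, SE 0.96; -8.64 to -6.17 with 1 library left out), endothelial cells from 6.94% ± 2.09 to 0.573% ± 0.370, fibroblasts from 29.0% ± 9.22 to 6.09% ± 4.50, neutrophils from 6.27% ± 3.26 to 1.83% ± 1.06 and plasmacytoid dendritic cells from 0.569% ± 0.265 to 0.151% ± 0.128. No DM cluster was named arachnoid barrier cell, Schwann or glial cell, mural cell, monocyte, erythroid cell, granulocyte-monocyte progenitor or stem cell, so that counts of named cells were at least 1480-, 828-, 331-, 255-, 217-, 50.3- and 29.9-fold lower than in nontumor. These bounds cover counting error only. None holds with marker scores per cell, where the share of arachnoid barrier cells fell with a log2 fold of -2.14 and the share of Schwann or glial cells with -2.17. Macrophages (24.0% ± 14.1 in DM, adjusted p = 0.0676), T cells (6.00% ± 5.34, adjusted p = 0.0545), NK or innate lymphoid cells (0.560% ± 0.475) and dendritic cells (1.65% ± 0.849) did not pass the test.

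Of the 19 classes, 14 passed between DM and nontumor, each with an exact permutation p of 0.1. With marker scores per cell 7 passed, a count that includes a class not among the 14. Those scores gave rises of monocytes (log2 fold 0.55), plasmacytoid dendritic cells (1.03), granulocyte-monocyte progenitors (0.76) and stem cells (1.22) that did not pass. Clusters without a name held 17.7% ± 8.26 of the DM cells. With those scores the falls of fibroblasts (-1.53), neutrophils (-1.08), mural cells (-1.23) and erythroid cells (-0.48) did not pass either, and those of B, endothelial, Schwann and arachnoid cells and both rises did. With TMM over class counts the falls of fibroblasts (-1.44), neutrophils (-0.60) and plasmacytoid dendritic cells (-0.64) did not pass. Without tumour-like and erythroid cells those of neutrophils (-1.21) and plasmacytoid dendritic cells (-1.32) did not. The neutrophil call ended without DM replicate 2 (-1.62) or nontumor replicate 1 (-1.26) or 3 (-1.99), as well as without nontumor replicate 2 (-1.96). The plasmacytoid call ended without DM replicate 1 (-1.34) or nontumor replicate 1 (-1.53) or 3 (-1.90). The replicate block ended the calls of fibroblasts (-2.48, adjusted p = 0.0576), neutrophils (-1.80, adjusted p = 0.155) and plasmacytoid dendritic cells (-2.19, adjusted p = 0.120).

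Macrophages of DM dura rose in Arg1 and in glycolysis genes and fell in genes of resident border macrophages, beyond the change in the other classes. Arg1 rose from 1.32 CPM ± 2.08 to 825 ± 113 (n = 3), a log2 fold of 9.74 (SE 1.00, adjusted p = 0.00019) and a class-relative one of 5.47, and AA467197 by 8.15 and 4.17. With 1 library left out, Arg1 ranged from 9.14 to 13.02, the highest without nontumor replicate 2, and AA467197 from 7.09 to 8.60. Relative to the other classes, 14 of 20 glycolysis and hypoxia genes rose, among them Vegfa (class-relative log2 fold 1.66), the vascular growth factor, Aldoa (1.44) and Ldha (1.43), and 15 when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). Of 9 measured resident border macrophage genes 6 fell, among them Cbr2 (-3.33), F13a1 (-2.89) and Pf4 (-2.47), and 8 when adjusted over the list alone (adjusted p = 0.284 with an estimated correlation). By the plain fold 18 of the 20 glycolysis genes rose and all 9 border macrophage genes fell. NF-kB inflammatory genes were lower relative to the other classes in 11 of 18 cases, 11 also when adjusted over the list alone (adjusted p = 0.378 with an estimated correlation). By the plain fold 2 of these 11 fell, and 5 of the 18 rose, so a fall of the list within macrophages is not shown. There Ccl3 stood at 416 CPM ± 224 in DM and 860 ± 221 in nontumor, a plain fold that did not pass. Heph, a copper ferroxidase, and Negr1, a neuronal adhesion protein, fell by 8.47 and 8.29 on the log2 scale, with class-relative folds of -2.18 and -2.12. The call of Negr1 ended without DM replicate 1 or 2 or any 1 nontumor library (-8.45 to -7.66). The DM macrophages came from other clusters than the nontumor ones, since the kits were clustered apart, and no monocyte cluster was named.

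Neutrophils of DM dura rose in interferon genes relative to the other classes and were lower in several granule genes. Of 16 measured interferon response genes 13 rose, among them Gbp2 (class-relative log2 fold 3.41), Ifi47 (2.76) and Rtp4 (2.48), and 13 when adjusted over the list alone (adjusted p = 0.308 with an estimated correlation); 10 of these 13 rose by the plain fold too. Of 10 neutrophil granule genes 6 fell, among them Chil3 (-4.36), Wfdc21 (-4.25) and the collagenase Mmp8 (-2.68), and 6 when adjusted over the list alone. Of these 6, 4 fell by the plain fold too, and fry did not call the list (adjusted p = 0.0572, and 0.553 with an estimated correlation in camera). All DM neutrophils lay in cluster 28, led by S100a9, S100a8, Retnlg and Ngp. Of nontumor neutrophils, 38.8% lay in cluster 16, led by the immature granule genes Camp and Ngp, and 50.9% in cluster 3. Relative to the other classes, the same interferon list was lower in monocyte-macrophages, with 12 of 20 genes lower and 13 when adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). In T cells 7 of 15 were lower and 1 higher, and 8 and 1 when adjusted over the list alone (adjusted p = 0.378 with an estimated correlation). The rise in neutrophils by itself lowers these relative values. By the plain fold 5 of the 12 fell in monocyte-macrophages and 0 of the 7 in T cells, and of all measured members 4 and 2 rose, so a fall of the list within either class is not shown. Itga3, an integrin chain, was at least 234-fold higher (class-relative 1.93), and Glcci1 and Foxred2 were at least 20.8- and 5.74-fold lower. For Itga3, transcripts of tumour-like cells were not separated from those of neutrophils. Car4, a carbonic anhydrase, had 188 UMIs in DM and 1 in nontumor, a ratio of CPM of 1148 (counting interval 204 to 45591). The call of Itga3 ended without nontumor replicate 1 or 3, that of Car4 without DM replicate 2 or 3, and that of Glcci1 without any 1 nontumor library, while the plain adjusted p stayed at 0.00404 and 0.00238, 0.00112 and 1.62e-05, and 0.00232 to 0.00319. With marker scores per cell the calls of Itga3, Car4, Glcci1 and Foxred2 all ended (plain adjusted p = 0.000407, 0.00421, 0.000315 and 0.00385). That of Car4 also ended with the first naming rule (0.000314) and that of Glcci1 with the replicate block (0.00137).

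T cells of DM dura fell in naive T cell genes and rose in Lag3 and Havcr2, which encode inhibitory receptors. Of 9 measured naive genes 6 fell relative to the other classes, among them Tcf7 (class-relative log2 fold -4.99), Il7r (-4.35) and S1pr1 (-2.93), and 7 when adjusted over the list alone (adjusted p = 0.266 with an estimated correlation); 5 of these 6 fell by the plain fold too, by which 2 other naive genes rose. Of the 17 members of the activation and exhaustion list, 8 entered the class-relative test. Among these Lag3 (4.97) and Havcr2 (4.18) rose, while Icos (-2.28), Il2ra (-2.44) and Ccl5 were lower relative to the other classes. Adjusted over the list alone, 2 were higher and 3 lower as well. As a list these 8 did not pass camera (adjusted p = 0.868), and the other members were not part of that test. Hspa1b, a heat shock protein, had 1273 UMIs in DM and 1 in nontumor, a ratio of CPM of 369 (counting interval 66.1 to 14592). Agtr1a, an angiotensin receptor, was at least 19.0-fold higher. In both rises, transcripts of tumour-like cells were not separated from those of T cells. Chrm3, a muscarinic receptor, was at least 172-fold lower, and Heph had a ratio of CPM of 0.000921 (counting interval 0.000111 to 0.00334). The call of Hspa1b ended without DM replicate 2 or 3 (plain adjusted p = 3.60e-05 and 3.20e-06) and with marker scores per cell (3.99e-05), that of Agtr1a without DM replicate 2 (0.000389), and that of Chrm3 without DM replicate 2 or 3 or nontumor replicate 1 or 2 (0.000264 to 0.000743). Of the nontumor T cells, 44.1% lay in the gamma-delta cluster 44, and the DM T cells lay in clusters led by Cd8a, Nkg7 and Pdcd1 (36.2% and 34.0%) and by Ctla4 and Icos (24.0%).

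Fibroblasts of DM dura held higher levels of inflammatory, chemokine, cell cycle and keratin transcripts, many of which also lead clusters of DM macrophages or tumour-like cells. Of 18 NF-kB inflammatory genes 16 rose relative to the other classes, among them Cxcl2 (class-relative log2 fold 4.42) and Tnfaip3 (3.69), and 17 when adjusted over the list alone (adjusted p = 0.378 with an estimated correlation). The risers include Il1b, Il1rn, Tnf, Nlrp3, Ccl3, Ccl4 and Cd83, genes of myeloid cells, and Cxcl2, Il1b and Tnf lead the DM macrophage clusters 19 and 33. Of the 16, Ccl3, Ccl4, Cd83 and Tnf lay under the limit of 0.2 for free RNA, which the lists do not apply, and Cxcl2 lay at 0.273 of the whole-library level and Tnfaip3 at 0.537. A rise in the fibroblasts themselves was not separated from transcripts of macrophages. Of 15 chemokine and cytokine genes 8 rose, among them the monocyte attractants Ccl7 (5.73) and Ccl2 (4.31), and Csf1 was lower relative to the other classes; adjusted over the list alone these were 8 and 1 (adjusted p = 0.433 with an estimated correlation). Ccl7 and Ccl2 are among the top 10 genes of the DM macrophage cluster 20, but stood above their whole-library levels in fibroblasts, at 2.99 and 2.35 times. Cell cycle genes rose in 17 of 20 cases, among them Pclaf (3.32) and Cenpa (3.15), and 17 when adjusted over the list alone (adjusted p = 0.433 with an estimated correlation). Cenpa, Ube2c, Ccnb1 and Birc5 are among the top 10 genes of the DM tumour-like clusters 6 and 16, and transcripts of tumour-like cells were not separated from those of fibroblasts. In monocyte-macrophages 19 of the 20 cell cycle genes were lower relative to the other classes, 19 also when adjusted over the list alone (adjusted p = 0.308 with an estimated correlation), while by the plain fold 4 of these 19 fell and 10 of the 20 rose. Collagen and matrix genes had 0 of 19 members past the class-relative test in limma, while by the plain fold, which carries the kit, 18 rose and 1 fell. Krt18 rose from 0.152 CPM ± 0.159 to 351 ± 230 (n = 3), and Krt7 had 3038 UMIs in DM and 3 in nontumor, a ratio of CPM of 3059 (counting interval 1046 to 14844). Both are tumour markers, and whole DM libraries held 1586 CPM ± 581 of Krt18 and 442 ± 14.0 of Krt7. Their fibroblast levels, 0.221 and 0.226 of the whole-library level, lay just above the limit of 0.2 for free RNA, and both calls ended with the first naming rule (plain adjusted p = 8.87e-05 and 7.43e-06) and without DM replicate 1 (0.000154 and 3.19e-05). Chad, a cartilage matrix protein (chromosome 11, 94565047 to 94569127), fell by 9.93 on the log2 scale (SE 0.80; -11.76 to -8.98 with 1 library left out), and Lypd6b had a ratio of CPM of 0.00189 (counting interval 4.78e-05 to 0.0105), a call that ended without nontumor replicate 2 or 3 (plain adjusted p = 0.000322 and 0.000258). The fibroblasts of the groups lie in different clusters: Chad leads cluster 39 with 20.3% of nontumor fibroblasts, and is among the top 10 genes of no DM fibroblast cluster.

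Endothelial cells of DM dura had higher levels of cell cycle genes and of part of the angiogenesis genes. The class held 121, 32 and 65 cells in DM replicates 1 to 3, against 2255 cells in the nontumor libraries together. Of 20 cell cycle genes 13 rose relative to the other classes, among them Ube2c (class-relative log2 fold 3.77) and Birc5 (3.68), and 17 when adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Ube2c, Birc5 and Pimreg are among the top 10 genes of DM tumour-like clusters, and transcripts of tumour-like cells were not separated from those of endothelial cells. In the angiogenesis list 6 of 11 genes rose, among them the vessel-destabilising factor Angpt2 (2.87), and Flt1, a VEGF receptor, fell (-2.49); adjusted over the list alone these were 7 and 3 (adjusted p = 0.308 with an estimated correlation). Of the 6 risers 5 rose by the plain fold too, by which 4 of the 11 fell. Pimreg, a mitotic regulator, was at least 105-fold higher, a call that ended without nontumor replicate 1 or 3 (plain adjusted p = 0.000105 and 9.94e-05). Hlf, a circadian transcription factor, was at least 87.8-fold lower, a call that ended without any 1 nontumor library (plain adjusted p of 0.000116 to 0.000201), and Col6a6, a collagen chain, was at least 54.5-fold lower.

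With both tests required, 4156 gene tests were called between DM and nontumor (2205 rises and 1951 falls): 1448 in fibroblasts (969 and 479), 1052 in neutrophils (457 and 595), 672 in monocyte-macrophages (341 and 331), 496 in endothelial cells (254 and 242) and 488 in T cells (184 and 304). The plain edgeR test alone called 26439. The neutrophil count was 677 and 682 without nontumor replicates 3 and 2 and 1894 without DM replicate 3, and the endothelial count was 318, 270 and 268 without nontumor replicates 1, 2 and 3. Of 38 pairs of list and class, camera at the preset correlation called 25 (11 higher and 14 lower), fry 18, and camera with an estimated correlation 0. At the preset correlation the other splits of the 6 libraries called between 14 and 27, the highest more than the real one. Median, mean and test differed in sign for 2 pairs, T cell activation and the immediate early list in endothelial cells.

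The comparison of DM with LM asks how the dura differs between carcinoma in the dura and in the inner meninges, again across kits. Tumour-like cells were 36.4% ± 10.4 in DM and 3.70% ± 2.99 in LM (n = 3), a log2 fold of 3.30 (SE 0.82, adjusted p = 0.0134; 2.81 to 4.06 with 1 library left out). Osteoclasts were at least 625-fold higher in DM (adjusted p = 0.000423), a bound that does not hold with marker scores per cell (log2 fold 3.17). B cells (log2 fold -4.44; -6.34 to -3.86 with 1 library left out), endothelial cells (-3.18), plasmacytoid dendritic cells (-3.09), NK or innate lymphoid cells (-2.21), fibroblasts (-2.20) and neutrophils (-1.62) were lower in DM. Arachnoid barrier cells, Schwann or glial cells, monocytes, mural cells, erythroid cells and granulocyte-monocyte progenitors had no named DM cluster, so that counts of named cells were at least 1575-, 272-, 264-, 238-, 37.3- and 29.7-fold lower. These bounds cover counting error only and do not hold with marker scores per cell. By those scores the share of arachnoid barrier cells fell with a log2 fold of -2.30 and the share of mural cells with -1.25. Erythroid cells were then higher in DM and passed (log2 fold 1.92, adjusted p = 0.0162). Granulocyte-monocyte progenitors (1.04), monocytes (-0.28), Schwann or glial cells (-0.94), B cells (-1.50), endothelial cells (-1.21), fibroblasts (-1.44), neutrophils (-0.88) and plasmacytoid dendritic cells (0.11) did not pass. With TMM over class counts fibroblasts (-0.77, adjusted p = 0.360), neutrophils (-0.51, adjusted p = 0.107) and plasmacytoid dendritic cells (-1.97, adjusted p = 0.0704) did not pass. Nor did fibroblasts without tumour-like and erythroid cells (-1.53, adjusted p = 0.0516). T cells, macrophages, dendritic cells and mast cells or basophils did not pass. Of 18 classes, 14 passed, each with an exact permutation p of 0.1, and 9 passed without LM replicate 2. With marker scores per cell 9 passed, a count that includes classes not among the 14 and erythroid cells in the opposite direction. Of the 14, tumour-like cells, osteoclasts, arachnoid barrier cells, mural cells and NK or innate lymphoid cells kept call and direction. Without LM replicate 2 the calls of B cells (-4.05), erythroid cells (-7.82), neutrophils (-1.64), plasmacytoid dendritic cells (-2.92) and NK or innate lymphoid cells (-2.17) ended. Without DM replicate 2 those of B cells (-4.13), fibroblasts (-1.93), neutrophils (-1.47), plasmacytoid dendritic cells (-3.28) and NK or innate lymphoid cells (-1.99) ended, and without LM replicate 1 that of neutrophils (-1.52). The replicate block also ended the neutrophil call (-1.77, adjusted p = 0.0859).

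Within classes, DM fibroblasts had lower levels than LM fibroblasts of Chad (log2 fold -9.16, class-relative -5.68) and Chrdl1, a BMP antagonist (-7.40 and -3.30). With 1 library left out these ranged from -10.97 to -8.22 and from -8.33 to -6.85. Chad and Chrdl1 are among the top 10 genes of clusters 39 and 37, with 14.2% and 17.3% of LM fibroblasts, and of no DM fibroblast cluster, so the class differs in its clusters. DM fibroblasts had higher levels of Krt7 (8.04 and 2.02) and Ankrd1 (7.81 and 2.56). Krt7 and Ankrd1 are among the top 10 genes of DM tumour-like clusters and stood in fibroblasts at 0.226 and 0.236 of the whole-library level, just above the limit for free RNA. Both calls ended with the first naming rule (7.098 and 6.49). Endothelial cells of DM had higher levels of the mitotic genes Pimreg (5.75) and Ccnb1 (5.21), and were at least 66.8-fold lower in Penk, which encodes enkephalin, and at least 49.5-fold lower in Hlf. Pimreg and Ccnb1 too are among the top 10 genes of a DM tumour-like cluster, and the Penk call ended with all 9 libraries in 1 fit (plain adjusted p = 0.0617). In neutrophils Car4 was at least 291-fold higher and Acp5, an osteoclast phosphatase, rose by 7.16 on the log2 scale (class-relative 3.01; 6.41 to 7.53 with 1 library left out), while Tex15 fell by 5.17 and Schip1 had a ratio of CPM of 0.0424 (counting interval 0.00511 to 0.155). Acp5 is among the top 10 genes of every DM osteoclast cluster, and transcripts of osteoclasts were not separated from those of neutrophils. In monocyte-macrophages Agtr1a rose by 5.91, Hist2h2bb, a histone gene, had a ratio of 141 (counting interval 48.1 to 686), and Negr1 and Heph fell with log2 folds of -8.27 and -8.14. T cells were higher in Hspa1b (6.76) and in Epha2, a receptor kinase, with a ratio of 179 (counting interval 31.4 to 7117). They were at least 89.0-fold lower in Dnah7a, a dynein chain, and had a ratio of 0.00102 (counting interval 0.000124 to 0.00371) in Heph. In the rises of Agtr1a, Hspa1b and Epha2, transcripts of tumour-like cells were not separated from those of the class. Calls that ended without any 1 LM library were those of Schip1 (plain adjusted p of 0.00760 to 0.00844), Heph in monocyte-macrophages (log2 folds -8.23 to -8.07), Epha2 (plain adjusted p of 0.000631 to 0.000871), Dnah7a (0.000580 to 0.000658) and Hlf (0.000479 to 0.000789). Those of Krt7 (7.66), Ankrd1 (6.86), Hist2h2bb (plain adjusted p = 0.000489), Hspa1b (6.90) and Ccnb1 (4.74) ended without DM replicate 1. The Hspa1b call also ended without DM replicate 2 (6.53) or 3 (6.82) or LM replicate 1 (6.45) or 3 (6.45), the Ccnb1 call without DM replicate 3 (5.19) or LM replicate 1 (4.68) or 2 (5.51), the Negr1 call without LM replicate 2 (-8.39) or 3 (-8.36), and the Pimreg call without LM replicate 1 (5.53) or 2 (5.43). With marker scores per cell the calls of Car4 (plain adjusted p = 0.0137) and Hspa1b (6.51) ended. With the replicate block those of Hist2h2bb (7.53) and Dnah7a (plain adjusted p = 0.000305) ended, and that of Dnah7a also with all 9 libraries in 1 fit (1.64e-06) and without the filter on low counts (8.84e-11).

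Both tests called 3736 genes between DM and LM (2010 rises and 1726 falls): 1450 in fibroblasts, 823 in neutrophils, 495 in monocyte-macrophages, 493 in endothelial cells and 475 in T cells. The total was 2246 without LM replicate 1 and 2428 without LM replicate 2. Without LM replicates 1, 2 and 3 in turn the counts were 371, 428 and 448 in neutrophils, 201, 213 and 254 in T cells, and 236, 235 and 305 in endothelial cells. The monocyte-macrophage count was 275 without LM replicate 1 and 315 without LM replicate 3, and the neutrophil count was 1700 without DM replicate 3.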

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

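The first naming rule, naming without the added classes and the denominator without unnamed cells were chosen after the data had been seen, as were the Scrublet score, the clustering resolution and the naming thresholds behind every result; the other alternatives were fixed before. Of 598 class shares under an alternative, 504 kept direction and side of the threshold, 87 became weaker and 7 reversed. Of 1148 values of named genes, 1046 stayed and 102 became weaker, and of 414 counts, 320 stayed within 1.5 times and 94 moved. T cell and tumour-like shares in LM kept their calls in every setting. Except where the setting itself shows it (fewer libraries, fewer conditions on a call), the cause was not tested.

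With marker scores per cell, 7 classes passed between DM and nontumor and 9 between DM and LM. Both counts include classes that were not called in the main setting. Log2 folds reversed to 0.76 for granulocyte-monocyte progenitors, 0.55 for monocytes, 1.03 for plasmacytoid dendritic cells and 1.22 for stem or progenitor cells between DM and nontumor, and to 1.92 for erythroid cells, 1.04 for granulocyte-monocyte progenitors and 0.11 for plasmacytoid dendritic cells between DM and LM. Gene counts were 6409 in all between DM and nontumor, and 1482 in neutrophils and 238 in T cells between DM and LM, and tumour-like cells were 25.9% in DM and 0.318% in nontumor. With 3 tumour markers sufficing, tumour-like cells were 57.0% in DM and 0.542% in nontumor. With the first naming rule, T cells had 203 genes between DM and LM.

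With all 9 libraries in 1 fit, 4 classes passed between LM and nontumor, and 87 genes in neutrophils, 454 in monocyte-macrophages, 290 in fibroblasts, 62 in endothelial cells and 2390 in all; T cells had 743 between DM and nontumor. Without the fold threshold, LM against nontumor gave 536 genes in neutrophils, 3153 in monocyte-macrophages, 966 in B cells, 3346 in T cells, 4324 in fibroblasts, 374 in endothelial cells and 12699 in all. DM against nontumor then gave 1805 in monocyte-macrophages, 805 in T cells, 2793 in fibroblasts and 7444 in all, and DM against LM 1605, 869, 2933 and 7222. Without the filter on low counts, LM against nontumor gave 376 in neutrophils, 731 in B cells and 306 in endothelial cells. DM against nontumor gave 1633 in monocyte-macrophages, 740 in T cells, 3841 in fibroblasts, 855 in endothelial cells and 8514 in all, and DM against LM 1212 in monocyte-macrophages, 3199 in fibroblasts and 6554 in all.

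The plain edgeR test alone called 3829 genes in neutrophils, 5737 in monocyte-macrophages, 4041 in T cells, 8127 in fibroblasts, 4705 in endothelial cells and 26439 in all between DM and nontumor, and 3436, 5181, 3844, 7285, 4415 and 24161 between DM and LM. The class-relative test alone called 1960 in neutrophils, 1326 in monocyte-macrophages, 996 in T cells, 896 in endothelial cells and 7247 in all between DM and nontumor, and 1609, 953, 1082, 864 and 6571 between DM and LM. With an estimated correlation between genes, 0 gene lists passed in LM and 0 in DM.

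Leaving out 1 library at a time, 3 to 12 classes passed between LM and nontumor, 10 to 17 between DM and nontumor and 9 to 17 between DM and LM. Gene counts between LM and nontumor ranged from 67 to 265 in neutrophils, 246 to 497 in B cells, 510 to 973 in fibroblasts, 77 to 150 in endothelial cells and 2879 to 3828 in all. Between DM and nontumor they ranged from 677 to 1894 in neutrophils, 268 to 616 in endothelial cells and 3018 to 5599 in all. Between DM and LM they ranged from 371 to 1700 in neutrophils, 275 to 724 in monocyte-macrophages, 201 to 593 in T cells, 235 to 547 in endothelial cells and 2246 to 5045 in all.

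Pairing of the samples by replicate number was not shown. Deviations of libraries with the same number correlated at -0.484 to 0.190 between LM and nontumor, -0.143 to -0.00903 between DM and nontumor and -0.00273 to 0.143 between DM and LM. In these comparisons 1, 0 and 3 of 6 libraries correlated best with their own number. With 3 libraries per group these values cannot exclude pairing. With the number as a replicate block, 7, 11 and 13 classes, 3263, 4018 and 3558 genes, and 36 and 25 gene lists passed.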

Other observations

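The tests of B cells against marrow, resident and erythroid cells, the splits of the libraries for gene counts, and the counts by the plain fold, were chosen after the results had been seen; the others were written before. In LM, immediate early genes, which respond within minutes to stimulation or handling, moved in opposite directions in different cells. B cells rose in 7 of 16 of them, among them Fosb (log2 fold 1.59), Fos (1.51) and Junb (1.30), and in 8 when adjusted over the list alone (adjusted p = 0.296 with an estimated correlation). Neutrophils rose in 5 of 16, among them Egr1 (2.09) and Dusp1 (1.35), and in 8 when adjusted over the list alone; fry did not call the list (adjusted p = 0.0736, and 0.344 with an estimated correlation in camera). T cells fell in 9 of 16, among them Jun (-1.37), and rose in 2, the same numbers as when adjusted over the list alone; fry did not call the list (adjusted p = 0.0745, and 0.417 with an estimated correlation in camera). Endothelial cells rose in 4 of 18 glycolysis and hypoxia genes, among them the glucose transporter gene Slc2a1 (1.24), and in 9 when adjusted over the list alone (adjusted p = 0.344 with an estimated correlation). Fibroblasts rose in 9 of 20 cell cycle genes, among them Pclaf (2.44) and Tyms (1.44), and in 18 when adjusted over the list alone; fry did not call the list (adjusted p = 0.0875, and 0.417 with an estimated correlation in camera). The cycling fibroblast clusters 32.2 and 32.3 held 0.976% and 1.01% of LM and 0.149% and 0.170% of nontumor fibroblasts, so the rise goes with a larger part of cycling cells in the class. Of 9 inflammatory monocyte genes in LM monocyte-macrophages, Ms4a4c rose (1.10) and 1 fell, and 1 and 1 when adjusted over the list alone (adjusted p = 0.883 with an estimated correlation).

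In DM, neutrophils rose in 7 of 18 immediate early genes relative to the other classes, among them Egr1 (class-relative log2 fold 3.94) and Jun (3.51), and in 9 when adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). Of 14 aged and tumour-associated neutrophil genes 9 rose, among them Cd274 (2.46) and Icam1 (1.88), and 3 fell, among them Cxcr4 (-2.13); adjusted over the list alone these were 9 and 3 (adjusted p = 0.458 with an estimated correlation). By the plain fold all 9 of these rose too and 1 of the 3 fell, and fry did not call the list (adjusted p = 0.0726). Monocyte-macrophages were lower in 4 of 8 inflammatory monocyte genes, among them Vcan (-3.33) and Ly6c2 (-2.71), and in 4 when adjusted over the list alone; fry did not call the list (adjusted p = 0.105, and 0.458 with an estimated correlation in camera). No DM cluster was named monocyte, while the nontumor class held 577 monocytes among 3322 cells. A fall of these genes within monocytes or within macrophages was not separated from this difference. Relative to the other classes, monocyte-macrophages were also lower in 13 of 18 immediate early genes, among them Jun (-2.34). Adjusted over the list alone these were 15 (adjusted p = 0.308 with an estimated correlation). By the plain fold, however, 3 of these 13 fell and 7 of the 18 rose. Endothelial cells rose in 6 of 19 collagen and matrix genes, among them Postn (2.69) and Sparc (2.06), while Fn1 was lower relative to the other classes; adjusted over the list alone these were 8 and 1, and fry did not call the list (adjusted p = 0.0726, and 0.378 with an estimated correlation in camera). Neutrophils were lower in 19 of 20 cell cycle genes relative to the other classes, 19 also when adjusted over the list alone (adjusted p = 0.266 with an estimated correlation), although by the plain fold 5 of these 19 fell, and Pclaf stood at 97.8 CPM ± 33.7 in DM and 103 ± 35.9 in nontumor (n = 3).

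Pinealocytes were 7.01%, 0.00844% and 0.0433% of the cells in nontumor replicates 1 to 3, 0.359%, 2.57% and 1.04% in LM, and 0 in DM. Olfactory cells were 1.36%, 0.676% and 0.805% in nontumor, 0.0534%, 0.946% and 5.18% in LM, and 0 in DM.

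The interferon genes could be higher in LM because of RNA released by other cells. The rise in CPM was divided by the largest rise that free RNA allows, and the median ratio over all measured genes of the list was 13.6 in monocyte-macrophages and 5.51 in neutrophils, with lower quartiles of 5.89 and 3.09. Free RNA within that bound cannot supply the rise of the list in these 2 classes. The ratio was 2.38 in fibroblasts, 2.02 in T cells and 1.96 in B cells, with lower quartiles of 0.847, 0.151 and 0.896, all under 1, which leaves the question open there. In endothelial cells it was 0.115, at a bound of 24.2% free RNA, so free RNA might account for the rise there.

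The smaller share of B cells in LM could come from less marrow carried along in the dissection or from dilution by incoming cells. Per marrow progenitor, B cells fell with a log2 fold of -1.84 (SD of the libraries 0.461 in LM and 1.01 in nontumor). Per fibroblast, endothelial, mural and Schwann or glial cell they fell with a log2 fold of -2.12 (SD 0.888 and 0.558). In both ratios every LM library lay below every nontumor library, which 3 against 3 libraries do by chance in 10% of cases. These values argue against dilution as the cause of the whole fall. Per marrow progenitor the gap was narrow. Nontumor replicate 1 held 1042 B cells to 70 granulocyte-monocyte progenitors and 28 stem or progenitor cells, and LM replicate 2 held 500 to 38 and 20. That ratio also counts only if progenitors come along in proportion, so less marrow stays open. Less blood or marrow as counted by erythroid cells stays open too. Erythroid cells fell as well (-2.52), as did mast cells or basophils (-1.83), and B cells per erythroid cell had a log2 fold of 0.118 (SD 0.743 and 1.05), a spread too wide to decide. The lower levels of Dntt and Rag1 and the smaller part of cluster 0 in LM would also arise if fewer developing B cells were present, which was not tested apart from the share.

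The kit may account for most genes that the plain test called between DM and nontumor. Their log2 folds correlated between classes with a median r of 0.708, against 0.341 between LM and nontumor, where the kit is the same. A change common to all classes in the tumour-bearing dura would give the same pattern. So would an effect of sequencing depth or counting software common to the classes. These values cannot tell such causes apart. For genes well counted in both groups, the class-relative test cancels what is common to the classes. A kit effect that differs between classes would remain. For genes with few or no counts in DM, a loss common to the classes cancels only in part. Falls called at such counts, such as those of Chrm3 and Heph in T cells, were not separated from such a loss.

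With 10 splits of 6 libraries, the splits are too few for a share under 0.05. The real split called 3707 genes between LM and nontumor, 4156 between DM and nontumor and 3736 between DM and LM, and the highest other split 3, 0 and 0. For cell classes the real splits called 10, 14 and 14 and every other split 0. In each of these, 1 split reached the real count, the real one. For gene lists the real split called 33 in LM against 25 in the highest other, with 1 split as large, and 25 in DM against 27, with 2 splits as large.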
